A study of Homo sapiens with 14 samples.

How the data were processed

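Total RNA was extracted with a column kit from subconfluent, untreated cultures and labelled as biotinylated cRNA with an Ambion MessageAmp Premier kit, per the labels' protocols, and hybridized to 1 Affymetrix array per cell line for 14 lines. The authors deposited 1 table of log2 expression values for 22277 probe sets on the 14 arrays. The values were made with RMA, per the submitters' processing notes, a method that corrects background, makes the distributions of all arrays alike and summarises the probes of each probe set; its software version and chip description are not given in the sources used here. That the values are on the log2 scale was read from their range. RMA gives no detection calls, it compresses differences between low values, and its equal distributions hide any difference in total RNA per cell. The number of arrays limits the precision, and no batch, slide or scan information is given in the sources used here, so batches could not be examined.

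Probe sets were named through the platform annotation, with symbols updated by gene identifier from a reference gene table of assembly GRCh38.p14, which was also used for the order of genes along chromosomes and for nothing else. Of the probe sets, 19070 had 1 gene symbol, 1043 had several and were not used, and 2164 had none; the identifiers of 19027 matched the reference table. Each gene was represented by the probe set with the highest mean over the arrays among those assigned to it alone, which gave 11939 genes. XIST, TSIX and genes of the Y chromosome, 24 genes, were left out of every step. A gene was kept if its highest value reached the median of all values, 7.01, which left 8623 genes. Probe sets of related genes can pick up more than 1 transcript, as in the MAGE and HLA families, and values of such genes are uncertain.

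Each line is a group of its own in the labels. Variation was described by the count of genes differing at least 4-fold between the highest and lowest line, similarity by Pearson's r across the 1000 genes with the largest SD after centring on the gene median, and distinctness by genes at least 3 log2 units above or below every other line. For chromosomal regions, the median deviation from the gene median was taken in windows of 15 neighbouring genes, and windows beyond the largest absolute value of 100 shuffles of gene order were merged. For 19 gene lists, the mean deviation of the genes was given with its SE over genes, and the list median was placed among those of 10000 random lists of the same size matched on level in 10 bins, for lists with at least 5 genes. The lists are luminal identity, estrogen-responsive genes, ERBB2 neighbourhood, basal epithelial, mesenchymal, epithelial junction, proliferation, interferon-stimulated, HLA class I and class II presentation, cholesterol synthesis, hypoxia and glycolysis, serine and one-carbon, ErbB receptors and ligands, cancer-testis, cell cycle inhibitors and tumour suppressors, immune cell markers, endothelial markers, and erythroid and hepatic markers. Relations between 20 fixed pairs of measures were tested 2-sided with 100000 permutations, or all permutations below 10 lines, and adjusted by Benjamini-Hochberg. Where a measure split the lines into separate clusters, at a gap above a fixed share of its range with at least 3 lines on each side, r was computed only within clusters of at least 6 lines. For the closing hypotheses, limma (lmFit and eBayes with trend) compared lines by what is commonly stated about them, an estrogen receptor class and a mesenchymal class that are not in the labels, and camera with a preset correlation of 0.01 tested the lists.

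The lists, thresholds, classes, alternatives and the rule for named genes were fixed before the data were examined. The rule named the 20 genes with the largest SD, for each line the 2 genes with the widest gap above and the 1 with the widest gap below the other lines, list and relation genes with the widest range or for which a list is known, the 5 genes with the largest deviation in a chromosomal region, and the 12 genes with the largest fold in each direction of a hypothesis. COL5A2, FBN1, HLA-C, KRT5, KRT15 and MCM3, which lie outside the 5 widest ranges of their lists, and the 12 genes drawn for their gap below the next line were chosen after their values were seen. Alternatives were the mean of a gene's probe sets, probe sets without an _x_at or _s_at suffix, no filter or a limit of 9.03, a second quantile normalization, arrays shifted to a common median, each line left out in turn, and other thresholds, window sizes, correlations, covariates and priors. Leaving out both HCC1428 and BT549 was added after seeing the data.

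The steps for variation, line-specific genes, chromosomal regions, list scores, relations, limma and camera were tested on simulated data, and the correlations between lines, Dixon's gap test and the test of neighbouring genes were not. Of 200 genes raised by 4 above the next line in 8623 genes, 200 were found in the right line with 0 others, and 200 of 200 genes made to vary were counted. These genes were placed beyond the thresholds and the others given little spread, so this checks the computation and not false calls in the real data. Shuffled gene order gave 0 regions and a planted block of 20 genes gave 1. Random lists fell outside the percentile range in 4.39% of combinations of list and line, and unrelated pairs had p under 0.05 in 5.25% of 400 permutation tests, against 100% of 200 pairs made with a correlation of 0.9. For the estrogen receptor classes, limma recovered 52%, 80%, 90% and 92% of genes changed by 1, 2, 3 and 4 log2 units, with 12 unchanged genes called. For the mesenchymal classes it recovered 36%, 74%, 86% and 94%, with 4 called. The planted list was found and 0 of 20 random lists were called in both. The simulated genes varied independently of each other, so these runs do not show how often camera calls lists whose genes vary together. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, matplotlib 3.10.9 for figures, and R 4.3.3 with limma 3.58.1. Probe sets with several symbols and genes below the limit in every line were left out of the results.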

Results

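Expression of 14 established human breast cancer cell lines, all untreated, was measured on 1 oligonucleotide array per line. The lines were BT483, BT20, MDA-MB-361, Hs578t, MDA-MB-231, MDA-MB-157, SKBR3, BT474, MCF7, HCC1806, T47D, ZR75, HCC1428 and BT549. The labels sort them into no further groups, so each line is its own group, and the comparisons below describe which genes and gene groups differed between lines. With 1 array per line no difference has a replicate check and none carries a p-value between lines. The deposited values are log2 expression per probe set, with array medians from 6.95 in BT549 to 7.06 in BT483 against a median of all values of 7.01. Added hybridization controls had a median SD of 0.12 across the arrays and added poly-A controls a median SD of 0.25, a measure of technical spread. Correlations between arrays over all 22277 probe sets ran from 0.849 to 0.958, and 0 pairs of arrays held identical values. The BT549 array had the largest 3-prime minus 5-prime difference for GAPDH, at 0.36 against 0.14 on the next array, and for ACTB, at 0.66 against 0.40.

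Among the 20 genes with the largest SD across the lines, IGFBP5, which encodes a secreted binding protein of insulin-like growth factors, led with an SD of 4.15 and ranged from 4.26 in MDA-MB-157 to 13.78 in BT483. AGR2, a disulfide isomerase of secretory epithelium, ranged from 4.16 in BT20 to 14.06 in BT483. KRT19, a simple epithelial keratin, ranged from 4.51 in MDA-MB-157 to 14.15 in BT483, and CDH1, the gene of E-cadherin, from 3.28 in MDA-MB-157 to 13.25 in ZR75. AXL, a receptor tyrosine kinase, was 13.49 in Hs578t and 4.51 in MCF7, and SPARC, a matrix glycoprotein, 13.36 in MDA-MB-157 and 4.47 in MCF7. CAV1, the main caveolar protein, reached 13.40 in BT549 and lay at 3.60 in T47D, and MSN, the gene of moesin, reached 11.75 in MDA-MB-231 and lay at 3.52 in MCF7. The gap junction gene GJA1 was highest in BT549 at 13.11, the collagenase gene MMP1 in MDA-MB-231 at 13.31 and HCC1806 at 12.64, and the pentraxin gene PTX3 in MDA-MB-231 at 11.95. SCGB2A2, which encodes the secreted mammaglobin A, stood at 13.32 in ZR75, 12.90 in BT474, 11.67 in MDA-MB-361 and 10.22 in SKBR3, and at 8.20 or less in the other 10 lines. S100A8, a calcium-binding protein of epithelial and myeloid cells, was highest in ZR75 at 14.73, and MGP, matrix Gla protein, in T47D at 14.13. The remaining genes of the 20 were GNG11, MAGEA6, TOX3, SRGN, CRIP1 and LXN. The probe set of MAGEA6 can pick up other members of its family.

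Of 8623 genes that passed the low-signal filter, 4412, or 51.2%, differed at least 4-fold between their highest and lowest lines, 2326 at least 8-fold and 513 at least 64-fold. Another 815 genes differed less than 2-fold, and the median SD across lines was 0.58. Restricting each gene to probe sets without an _x_at or _s_at suffix, which removes genes as well as probe sets, lowered the 4-fold count to 2854. For 1353 genes in the 4-fold group a further probe set was above the limit, and its median correlation with the one used was 0.959; for 86 of them, 6.36%, it fell below 0.5.

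Genes that define the hormone receptor, ERBB2 and mesenchymal states of breast cancer cells separated the lines widely. ESR1, the gene of estrogen receptor alpha, stood at 11.55 in MCF7, 11.54 in MDA-MB-361, 11.46 in T47D, 11.21 in BT483, 9.56 in BT474 and 8.84 in ZR75. It was 7.87 in BT20, 7.83 in HCC1428, 6.73 in HCC1806 and 6.47 in SKBR3, and between 3.65 and 4.68 in MDA-MB-157, MDA-MB-231, Hs578t and BT549. PGR, the progesterone receptor gene, reached 10.31 in T47D and 9.86 in BT483, while the third highest value was 7.02 in BT474, close to the low-signal limit of 7.01. ERBB2, the gene of the HER2 receptor, was highest in BT474 at 14.02, SKBR3 at 13.80 and MDA-MB-361 at 13.30, and EGFR, the gene of the epidermal growth factor receptor, in BT20 at 12.31. VIM, the gene of vimentin, lay between 14.12 and 14.75 in Hs578t, MDA-MB-231, MDA-MB-157 and BT549 and did not exceed 8.96, its value in HCC1428, elsewhere. In those 4 lines ZEB1, a transcriptional repressor of CDH1, lay between 8.43 and 9.80, against 5.46 or less in the other 10, and CDH1 lay between 3.28 and 4.50, against 9.78 in SKBR3 and 10.98 or more in the other 9. Low values such as these are compressed by the array's background, so differences that reach them may understate the true fold.

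**Figure D1:**
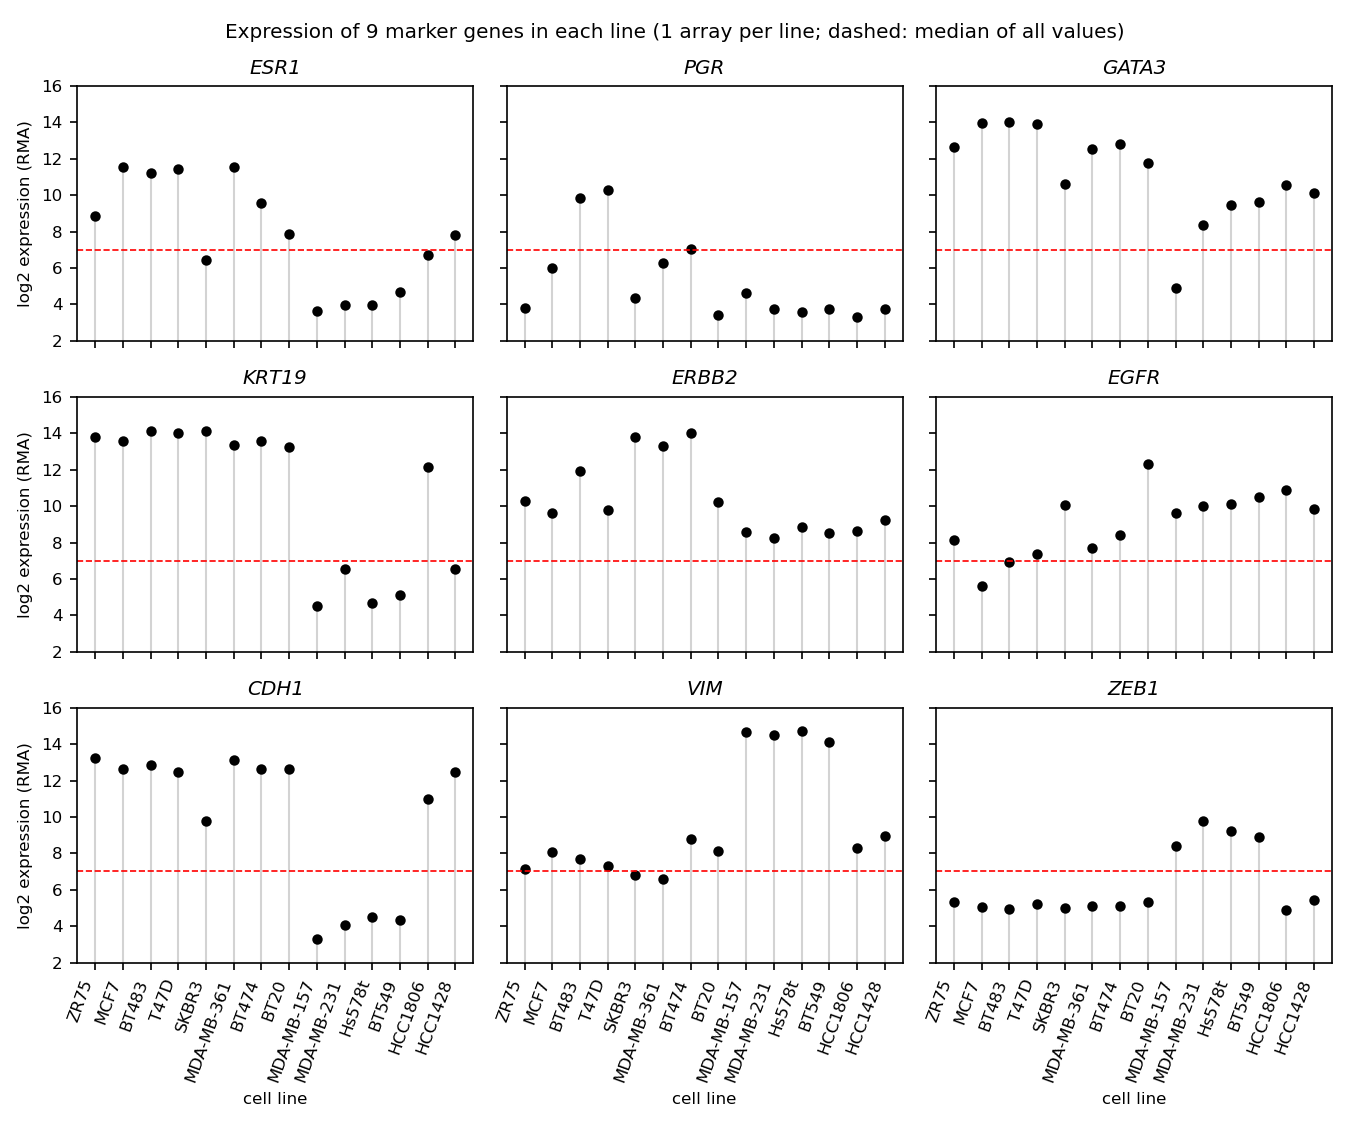
Log2 expression (vertical axis) of 9 marker genes in each of the 14 cell lines (horizontal axis), 1 point per array, with a dashed line at the median of all values, 7.01. VIM and ZEB1 are highest, and CDH1 lowest, in the same 4 lines, while ERBB2 exceeds 13 in BT474, SKBR3 and MDA-MB-361.

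Gene lists fixed before the data were examined were scored in each line as the mean deviation of their genes from each gene's median over the lines, given here with the SE over genes. The luminal identity list, 14 measured genes of the luminal breast epithelium, was highest in BT483 at 1.73 ± 0.39 and positive in MDA-MB-361, BT474, T47D, MCF7, ZR75 and SKBR3, and lowest in MDA-MB-157 at -3.03 ± 0.71, with Hs578t, BT549 and MDA-MB-231 between -2.96 and -2.75. Sizes of the intermediate luminal scores depended on which lines were included: with any other line left out in turn, the score of SKBR3, 0.68, ran from 0.28 to 1.09, that of ZR75, 0.80, from 0.39 to 1.21, that of MCF7, 1.05, from 0.64 to 1.45 and that of HCC1806, -1.04, from -1.44 to -0.63, with the lowest values where BT549, Hs578t, MDA-MB-157 or MDA-MB-231 was left out. GATA3, a luminal transcription factor, ranged from 14.03 in BT483 to 4.93 in MDA-MB-157, and FOXA1, a pioneer factor for estrogen receptor binding, from 11.25 in BT474 to 5.06 in BT549. HCC1428 scored -1.26 ± 0.46 and had 7 luminal genes at least 1 below their median and 0 at least 1 above. The estrogen-responsive list, 18 genes, was highest in T47D at 2.26 ± 0.59, BT483 at 2.01 ± 0.55 and MCF7 at 1.66 ± 0.48, and lowest in BT20 at -1.32 ± 0.34. TFF1, a secreted trefoil peptide, reached 13.72 in MCF7 and 13.66 in BT483, and GREB1, a cofactor of the receptor, 10.02 in MCF7 and 10.01 in T47D. Hs578t, in which ESR1 was 3.99, had a positive score of 0.70 ± 0.45 (0.43 without HCC1428 and BT549), with 6 of its 18 genes at least 1 above their median.

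The mesenchymal list, 25 genes that are also markers of fibroblasts, was highest in Hs578t at 5.13 ± 0.49, where all 25 lay at least 1 above their median, followed by BT549 at 3.75 ± 0.51, MDA-MB-157 at 2.78 ± 0.45 and MDA-MB-231 at 2.06 ± 0.47. The matrix genes COL3A1, COL6A3, COL1A2 and FBN1 were highest in Hs578t, at 14.55, 14.17, 14.33 and 12.74, while COL5A2 was highest in BT549. HCC1806 and HCC1428 had intermediate mesenchymal scores of 1.0 ± 0.27 and 1.0 ± 0.28, and BT483 the lowest at -1.52 ± 0.34. The epithelial junction list, 19 genes, was lowest in the same 4 lines, from -4.21 ± 0.46 in Hs578t to -3.58 ± 0.49 in MDA-MB-231, with all 19 genes at least 1 below their median in Hs578t and in BT549. EPCAM, an epithelial adhesion molecule, was 3.89 in Hs578t against a median of 12.11, and ESRP1, an epithelial splicing regulator, 4.32 against 10.01. The basal epithelial list, 12 genes of basal and myoepithelial cells, was highest in HCC1806 at 3.46 ± 0.71, HCC1428 at 2.76 ± 0.46 and BT20 at 1.33 ± 0.46. The basal keratin KRT5 was 11.86 in HCC1806 and 11.35 in BT20 and 6.94 in HCC1428, whereas KRT15 was highest in HCC1428 at 11.13. KRT14, a further basal keratin, was 11.71 in HCC1806 and 11.56 in Hs578t.

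The ERBB2 neighbourhood list, 12 genes next to ERBB2 on chromosome 17, scored 2.77 ± 0.38 in BT474, 2.59 ± 0.56 in SKBR3 and 1.26 ± 0.39 in MDA-MB-361, with 11, 9 and 6 of the 12 genes at least 1 above their median; with probe sets lacking an _x_at or _s_at suffix the SKBR3 score was 1.67. GRB7, an adaptor of receptor kinases, reached 11.42 in SKBR3 and 11.24 in BT474, and the pore-forming gasdermin gene GSDMB 12.89 in SKBR3, although its other probe set deviated by only 0.79 there and had a gap of -1.47 to the highest other line. Among 8 genes of ErbB receptors and ligands, scored highest in HCC1806 at 1.79 ± 1.03 and lowest in BT549 at -0.78 ± 0.72 (-0.26 with the mean of each gene's probe sets), EREG, the gene of the ligand epiregulin, was 11.06 in HCC1428 and 10.35 in HCC1806 against 7.01 in the next line. HBEGF, another ligand of EGFR, was above 11 in MDA-MB-231, HCC1806 and HCC1428, at 11.94, 11.28 and 11.22, and ERBB3 was highest in BT483 at 11.84 and lowest in Hs578t at 3.75.

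**Figure D2:**
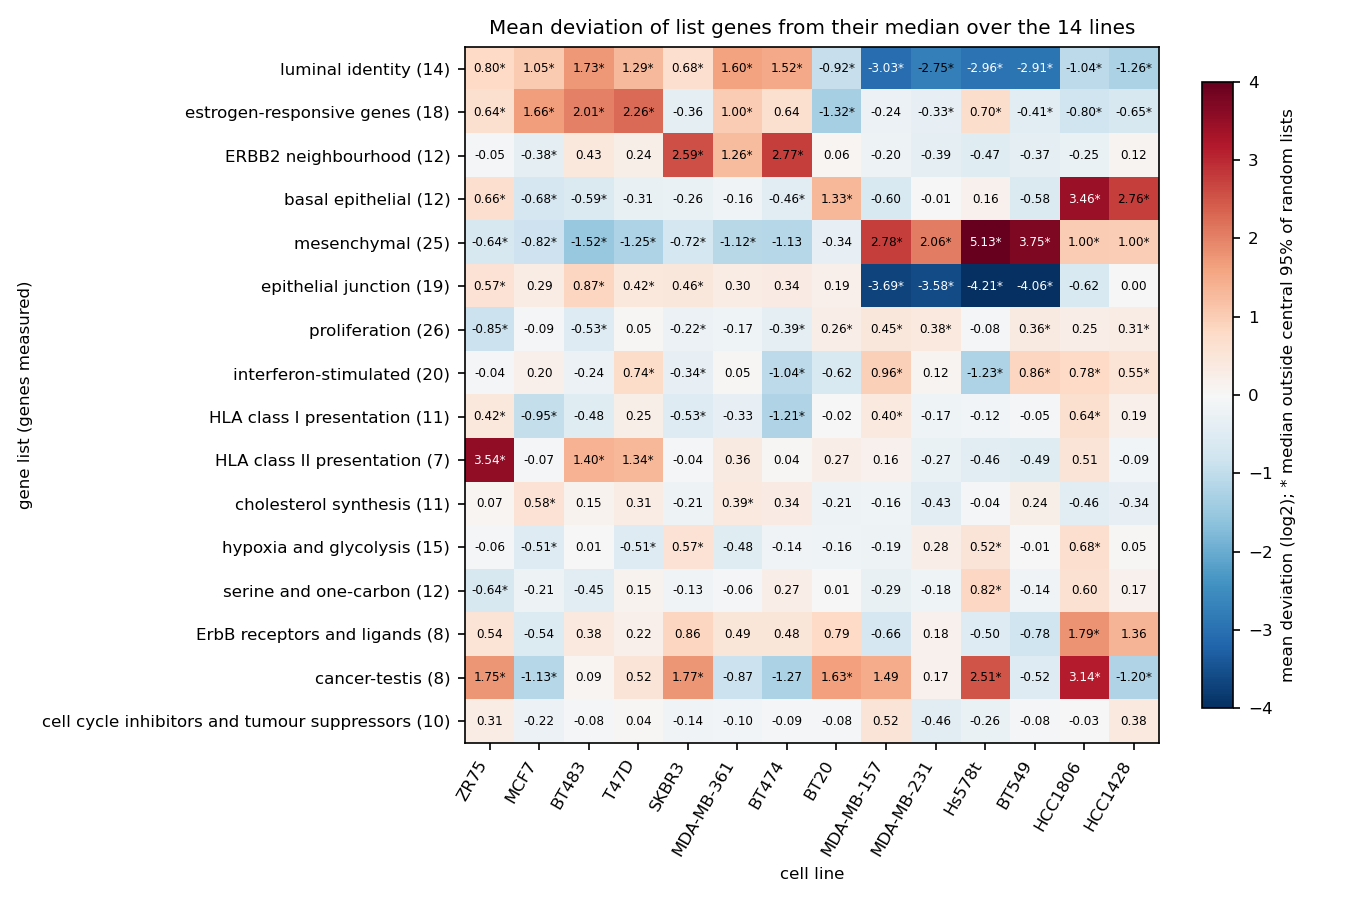
Mean deviation of the genes of each list (vertical axis, genes measured in brackets) from their medians over the 14 lines, on the log2 scale, for each cell line (horizontal axis), where a star marks a list median outside the central range of 10000 random lists. The mesenchymal score runs from -1.52 in BT483 to 5.13 in Hs578t and the HLA class II score reaches 3.54 in ZR75.

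Antigen presentation genes stood out in single lines. The HLA class II list, 7 genes, scored 3.54 ± 0.50 in ZR75, with all 7 at least 1 above their median, then 1.40 ± 0.43 in BT483 and 1.34 ± 0.44 in T47D, and lowest in BT549 at -0.49 ± 0.25. HLA-DRA was 10.26 in ZR75 against a median of 4.89, and CD74, the invariant chain, 11.15 against 6.26. The HLA class I list, 11 genes, was highest in HCC1806 at 0.64 ± 0.12 and lowest in BT474 at -1.21 ± 0.24. By the list median MDA-MB-157 was highest, at 1.21 against 0.67 in HCC1806, with 7 of its 11 genes at least 1 above their median, while its mean was 0.40 ± 0.99. In MDA-MB-157 HLA-B and HLA-C had their highest values of all lines, 14.09 and 13.75, while B2M, the light chain needed to bring class I molecules to the surface, was 3.86 against 12.41 in the next lowest line. Interferon-stimulated genes, 20 in the list, were highest in MDA-MB-157 at 0.96 ± 0.28, BT549 at 0.86 ± 0.26, HCC1806 at 0.78 ± 0.26 and T47D at 0.74 ± 0.23, and lowest in Hs578t at -1.23 ± 0.25 and BT474 at -1.04 ± 0.29. MX1, an antiviral GTPase, ranged from 10.39 in T47D to 5.02 in Hs578t. The cancer-testis list, 8 genes normally restricted to germ cells, was highest in HCC1806 at 3.14 ± 0.77 and Hs578t at 2.51 ± 0.57 and lowest in BT474 at -1.27 ± 0.77 (-0.79 with no filter), with MAGEC2 and CTAG2 highest in MDA-MB-157 at 11.78 and 10.81.

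Growth and metabolic lists spanned narrower ranges. The proliferation list, 26 genes, ran from 0.45 ± 0.11 in MDA-MB-157 to -0.85 ± 0.11 in ZR75, where 7 genes lay at least 1 below their median, among them the replication helicase genes MCM3 at 8.81 and MCM7 at 8.61. Cholesterol synthesis, 11 genes, ran from 0.58 ± 0.16 in MCF7 to -0.46 ± 0.17 in HCC1806, and hypoxia and glycolysis, 15 genes, from 0.68 ± 0.17 in HCC1806 to -0.51 ± 0.23 in T47D, but with probe sets lacking an _x_at or _s_at suffix HCC1806 scored 0.38, below MDA-MB-231 at 0.54, and MDA-MB-361 -0.79. The serine and one-carbon list, 12 genes, was highest in Hs578t at 0.82 ± 0.27 and lowest in ZR75 at -0.64 ± 0.18, and PHGDH, the entry enzyme of serine synthesis, ranged from 11.05 in BT20 to 5.53 in MDA-MB-231. Cell cycle inhibitors and tumour suppressors, 10 genes, did not move as a group in any line, with scores from 0.52 ± 0.49 in MDA-MB-157 (0.23 to 1.07 over the settings) to -0.46 ± 0.35 in MDA-MB-231 and 0 lines outside the range of random lists. Single members did differ. CDKN2A, which encodes the cell cycle inhibitor p16, was 12.29 in BT549, 11.54 in HCC1428 and 11.20 in MDA-MB-157 against a median of 7.76, and MTAP, its neighbour on chromosome 9, was lowest in MDA-MB-231 at 5.07 and MCF7 at 5.09. RB1, the retinoblastoma gene, was 3.53 in BT549 and 9.02 or more in the other 13 lines on the probe set used, while its other probe set read 9.19 in BT549 against a median of 5.49. PTEN and TP53 had no probe set assigned to them alone and are left without a value.

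Most markers of other cell types stayed below the low-signal limit. Of 15 immune cell markers with a probe set, 1 reached the low-signal limit, CD14 in MDA-MB-157 at 8.88. Among 9 endothelial markers ENG, which epithelial and mesenchymal cells can also express, reached it in 10 lines and was highest in MDA-MB-231 at 10.82, while CDH5, the endothelial cadherin gene, was 10.79 in BT20, TIE1 9.02 in MDA-MB-231 and PECAM1 7.41 in HCC1428. The erythroid and hepatic list, 6 genes, had TTR at 7.15 in SKBR3 and HBB at 7.06 in BT549 as its values above the limit. These 3 lists had fewer than 5 genes above the limit and were given no score. Across the other 16 lists, 99 of 224 combinations of list and line had a median in the outer 2.5% on either side of random lists of the same size and level. Lists of genes drawn at random would give 11.2. Genes that vary together give more extreme medians than genes drawn at random, and the combinations are not independent, so the excess is a description only. By the list median in place of the mean, 6 lists had another highest line. These were luminal identity (BT474, 1.57), estrogen-responsive genes (BT483, 1.5), interferon-stimulated genes (BT549, 0.83), HLA class I (MDA-MB-157, 1.21), cancer-testis genes (Hs578t, 2.97) and cell cycle inhibitors (ZR75, 0.19). Another 8 had a different lowest line, namely luminal identity and HLA class II (Hs578t, -2.15 and -0.43), the ERBB2 neighbourhood (MCF7, -0.37), basal epithelial (BT474, -0.76), hypoxia (MDA-MB-361, -0.31), ErbB (MDA-MB-157, -0.36), cancer-testis (HCC1428, -0.63) and cell cycle inhibitor genes (BT483, -0.34). Mean and median differed in sign in 21 of the 224 combinations, among them ErbB genes in HCC1428 (1.36 and -0.02), cancer-testis genes in MDA-MB-157 (1.49 and -0.03) and cell cycle inhibitors in MDA-MB-231 (-0.46 and 0.05).

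Lines resembled each other in a luminal and a mesenchymal block, with HCC1806, HCC1428 and BT20 outside the luminal one. Across the 1000 most variable genes, each centred on its median, Hs578t and BT549 were nearest to each other at r = 0.648 across genes, and MDA-MB-361 and BT474 at 0.636. HCC1806 and HCC1428 were nearest to each other at 0.529, and BT483 and T47D at 0.502. MDA-MB-231 was nearest to Hs578t at 0.589, MDA-MB-157 to BT549 at 0.556, SKBR3 to BT474 at 0.475 and MCF7 to BT483 at 0.369. ZR75 and BT20 resembled no line closely, with highest values of 0.289 to SKBR3 and 0.213 to HCC1428. The lowest value was -0.38, for BT483 and MDA-MB-231, 40 of the 91 pairs lay above 0, and the median was -0.065. Centring each gene on its median over the same lines pulls these values below 0 on average, so their signs are relative to this set of lines. Over all probe sets without centring, pairs of arrays correlated at 0.849 to 0.958. Genes are not independent replicates, so these values rank the lines without a test. With probe sets lacking an _x_at or _s_at suffix or with all filtered genes MCF7 was nearest to MDA-MB-361. ZR75 was nearest to BT483 with all filtered genes and to MDA-MB-361 with the 300 most variable, and BT483 to BT474 by Spearman's rho, while the other 11 lines kept their nearest line in these settings and in the other processing settings with all 14 lines.

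**Figure D3:**
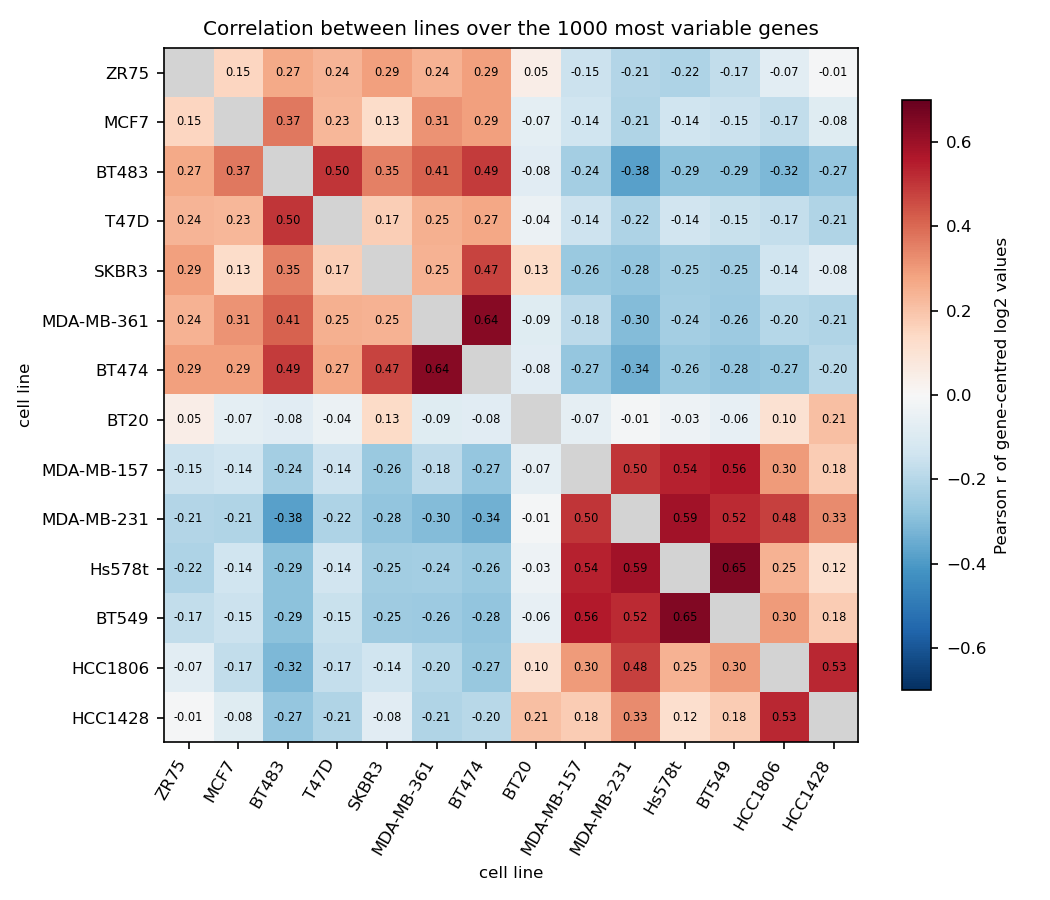
Pearson correlation across genes between each pair of the 14 cell lines (both axes), over the 1000 genes with the largest SD after centring each gene on its median, with red for positive and blue for negative values. The highest values are 0.65 for Hs578t with BT549 and 0.64 for MDA-MB-361 with BT474.

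Single lines stood at least 8-fold above every other line in 89 genes, with the largest numbers in Hs578t, 23, and ZR75, 10, and 0 in BT474. In Hs578t the matrix proteoglycan gene DCN was 12.12 against 6.14 in BT549, the next line, and the sodium channel gene SCN3A 9.07 against 3.23. THBS2, a matrix thrombospondin, was 12.17 in BT549 against 5.11 in the next line, and the collagen gene COL15A1 13.01 against 8.38. ZR75 was set apart by MGAM, an intestinal glucosidase, at 10.65 against 6.33, and SPRR3, a cornified envelope protein, at 11.76 against 7.49. In T47D SERPINA6, the corticosteroid-binding globulin gene, was 12.85 against 7.49 and TP53I3 13.30 against 9.47. In MDA-MB-361 the cancer-testis gene MAGEA8 was 10.77 against 4.74 and AMBP 13.44 against 7.60, although the AMBP gap of 5.83 fell to 0.44 with probe sets lacking an _x_at or _s_at suffix. HCC1806 had MAGEA4 at 9.30 against 3.63 and the lipoxygenase gene ALOX12 at 9.46 against 5.03. BT20 had the steroid dehydrogenase gene HSD3B1 at 9.35 against 4.42 and the aldo-keto reductase gene AKR1B10 at 13.81 against 9.46. MDA-MB-231 had ANKRD1, a muscle ankyrin repeat gene, at 11.56, a gap of 5.56, and TIE1, an endothelial receptor kinase gene, at 9.02 against 4.33. BT483 had SPAG6, a sperm flagellum gene, at 10.27 against 4.79 and RTN1 at 10.21 against 6.20. The genes with the widest gap were BEX1 at 11.42 and the tight junction gene CLDN10 at 9.19 in MDA-MB-157, ARL14 at 10.73 and the proprotein convertase gene PCSK5 at 9.78 in HCC1428, the chemokine receptor gene CX3CR1 at 9.23 and the deiodinase gene DIO1 at 10.29 in SKBR3, and BCAS3 at 12.55 and IGSF1 at 9.40 in MCF7. Probe sets without an _x_at or _s_at suffix gave 55 such genes and a gap of 4-fold in place of 8-fold gave 228.

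In 55 genes a single line lay at least 8-fold below all others, with 15 of them in MDA-MB-157, 7 each in BT20, T47D and BT549, and 0 in ZR75. The widest gap belonged to B2M in MDA-MB-157, 3.86 against 12.41 in the next lowest line, and a further probe set of the gene showed a gap of 8.15. TPD52, a vesicle trafficking gene, was 3.69 in Hs578t against 10.35, TMCO1, an endoplasmic reticulum calcium channel gene, 4.88 in BT474 against 11.47, and ME1, cytosolic malic enzyme, 4.98 in T47D against 9.95. RB1 was 3.53 in BT549 against 9.02, but its other probe set above the limit read 9.19 in BT549 against a median of 5.49 in the other 13 lines, the opposite direction. The glutathione transferase gene GSTM3 was 4.89 in BT20 against 9.39, the tubulin gene TUBB6 4.74 in BT483 against 8.97, SHLD2, a DNA end-protection gene, 4.74 in HCC1428 against 9.58, and the calponin gene CNN3 3.38 in MCF7 against 8.11. KLHL9, a ubiquitin ligase adaptor gene on chromosome 9, was 3.49 in MDA-MB-231 against 8.48, and its gap narrowed to 2.17 on the other probe set. KCTD9 in HCC1806, TRIP6 in MDA-MB-361 and ARMCX3 in SKBR3 were lower than the next line by 3.47, 4.02 and 3.53. Probe sets without an _x_at or _s_at suffix gave 27 such genes and a gap of 4-fold gave 116.

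**Figure D4:**
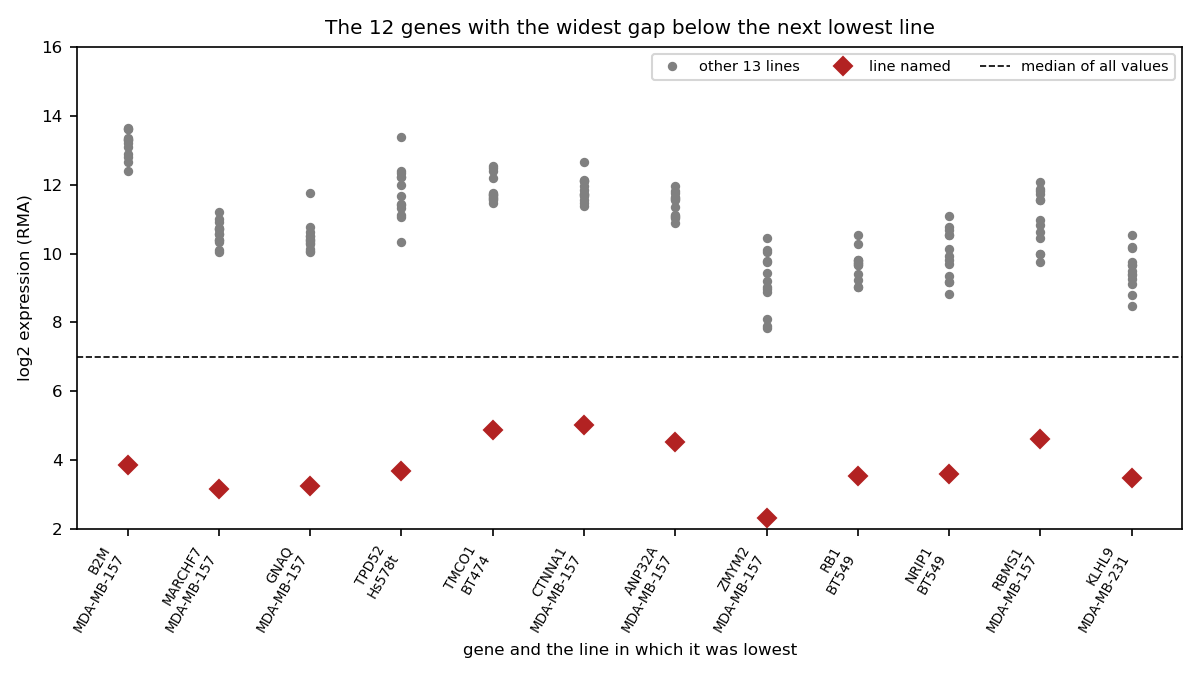
Log2 expression (vertical axis) of the 12 genes with the widest gap below the next lowest line (horizontal axis, with the line in which each was lowest), where the diamond is the named line, grey points are the other 13 lines and the dashed line is the median of all values, 7.01. B2M in MDA-MB-157 lies at 3.86 and in the other lines between 12.41 and 13.64.

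Neighbouring genes were high or low together in 43 chromosomal regions, 37 higher and 6 lower, spread over 12 lines. Gene order was taken from a reference annotation of assembly GRCh38.p14, and a region is a run of windows of 15 genes whose median deviation exceeded every one of 100 shuffles of gene order. On chromosome 17, BT474 had 36 genes from CCL4 to WIPF2 around ERBB2, with a strongest window median of 3.10, and SKBR3 26 genes from PIP4K2B to SMARCE1, with 2.58. PGAP3 and ERBB2 deviated by 4.47 and 4.31 in BT474, and GSDMB and GRB7 by 6.67 and 4.33 in SKBR3, where the other probe set of GSDMB deviated by 0.79. In MCF7 a region of 31 genes from VEZF1 to CCDC47 reached 3.16, led by BCAS3 at 5.91, the transcription factor gene TBX2 at 4.15 (1.23 and 2.76 on its other probe sets) and the phosphatase gene PPM1D at 3.70. Genes of the same stretch formed regions in BT474, from SRSF1 to TANC2, and in MDA-MB-361, from CUEDC1 to TLK2, and RNF43, a regulator of Wnt receptors, deviated by 3.11 and 3.23 there. MDA-MB-361 had 0 regions around ERBB2 itself. On chromosome 20, BT474 was higher from DPM1 to CTSZ, led by DOK5 at 4.97 and BCAS1 at 3.74, and lower from MYL9 to SNHG17, led by MYL9 at -3.55 and RBL1 at -3.20.

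Other regions included clustered gene families as well as mixed stretches. ZR75 was higher on chromosome 1 from TUFT1 to CHTOP, the cluster of epidermal differentiation genes, with SPRR1B deviating by 7.46 and S100A7 by 6.69, and parts of this cluster were also higher in SKBR3 and HCC1428. The chemokine cluster on chromosome 4 was higher in HCC1806, with CXCL6 at 7.63, and in ZR75, with CXCL1 at 5.11. BT483 was higher on chromosome 8 from GSR to GOLGA7, where RAB11FIP1 deviated by 3.80 and ERLIN2 by 3.41, and BT549 from SFTPC to GTF2E2, where LOXL2, a matrix crosslinking enzyme, deviated by 4.19. EGFR lay in a higher region of BT20 on chromosome 7, with a deviation of 2.57 (0.80, 0.82 and 2.91 on its other probe sets), CD44 in one of HCC1806 on chromosome 11, with 2.69, and CDKN2A in one of BT549 on chromosome 9, with 4.53. Regions of lower expression were found in SKBR3 on chromosome 8, led by MATN2 at -2.72, in HCC1428 on chromosomes 2 and 18, led by AGAP1 at -5.33 and RPRD1A at -1.99, and in MCF7 on chromosomes 1 and 18, led by SMYD2 at -1.37 and PIGN at -2.03. MDA-MB-157 and T47D had 0 regions. The median over all genes of the ZR75 region from TUFT1 to CHTOP was 0.97, and that of its chemokine region from CXCL8 to CXCL11 2.06. Both moved by more than the hybridization control spread of 0.12 in 17 of 20 settings, 13 of them single lines left out, over ranges of 0.67 to 2.15 and 1.5 to 2.5. Of the 43 regions, 14 had a median that moved by over 1.5 times in at least 1 setting. The HCC1806 chemokine region from UTP3 to NUP54 ran from 0.14 to 0.64 around 0.58, and the lower regions with MATN2, SMYD2 and PIGN from -1.42 to -0.80, -1.19 to -0.56 and -1.20 to -0.48. With the stricter filter the medians of the SKBR3 region from PIP4K2B to SMARCE1 and the BT474 region from SRSF1 to TANC2 were 1.95 and 1.96 in place of 0.98 and 1.13, and with probe sets lacking an _x_at or _s_at suffix that of the BT483 region from GSR to GOLGA7 was 1.19 in place of 0.60. The number depended on the window, with 21 regions for windows of 9 genes and 117 for 25, and rose to 65 when arrays were shifted to the same median.

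**Figure D5:**
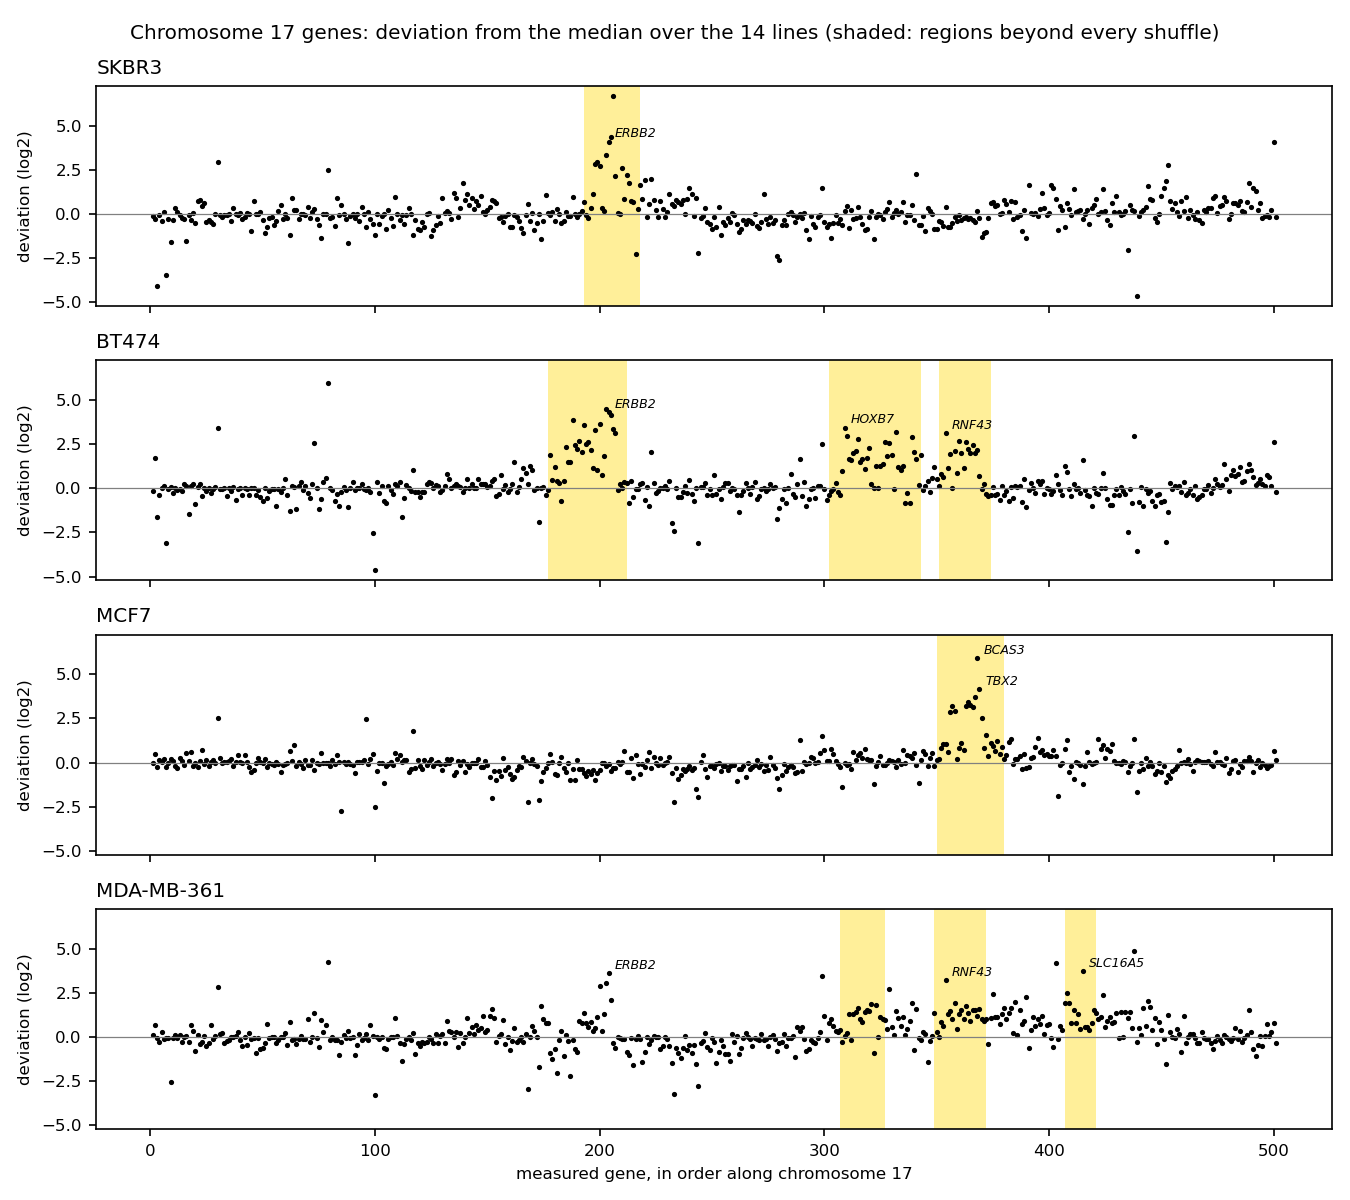
Deviation of each measured gene from its median over the 14 lines (vertical axis, log2), in order along chromosome 17 (horizontal axis), in SKBR3, BT474, MCF7 and MDA-MB-361, with regions beyond every shuffle shaded. The shaded regions around ERBB2 reach window medians of 2.58 in SKBR3 and 3.10 in BT474, and the region with BCAS3 3.16 in MCF7.

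Relations between marker genes and list scores fixed in advance were tested by permutation in a family of 27 tests, 2-sided, of which 10 had a Benjamini-Hochberg adjusted p under 0.05 by Pearson's r and 5 by Spearman's rho. ERBB2 and GRB7 varied together over the 14 lines, with r = 0.938 (permutation p = 1e-05, the smallest the permutations can give, adjusted p = 0.00027), rho = 0.877, and r = 0.88 without the 2 lines farthest from the median. GATA3 and FOXA1 did so with r = 0.842 (permutation p = 6e-05, adjusted p = 0.00081), rho = 0.881, and r = 0.856 without those 2 lines. ESR1 and PGR had r = 0.713 (permutation p = 0.0026, adjusted p = 0.014) and rho = 0.569 (adjusted permutation p = 0.11), and r = 0.75 without MDA-MB-231 and MDA-MB-157, the 2 lines farthest from the median on ESR1. That check kept T47D and BT483, whose PGR values of 10.31 and 9.86 stood far above the next, 7.02 in BT474. EGFR was lower where ESR1 was higher, with r = -0.728 (permutation p = 0.0035, adjusted p = 0.016) and rho = -0.688, but r was -0.615 and no longer passed without BT483 and MCF7, and it was -0.053 with probe sets lacking an _x_at or _s_at suffix. CDKN2A and RB1 were opposed, with r = -0.647 (permutation p = 0.00043, adjusted p = 0.0039) and rho = -0.556, but the relation no longer passed without HCC1428 and BT549, with r = -0.546 and an adjusted permutation p of 0.17, or without BT549 alone, with r = -0.654 and an adjusted permutation p of 0.057, and the 2 RB1 probe sets disagreed in BT549. ZEB1 splits the lines 4 against 10, so no pooled value with CDH1 is given; within the 10 lines of lower ZEB1, r was 0.446 (permutation p = 0.2, adjusted p = 0.3), rho 0.224, and r 0.428 without ZR75 and HCC1428.

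Among the list scores, relations involving a measure that splits the lines into separate clusters were tested only within clusters of at least 6. Within the 10 lines of higher epithelial junction score, that score and the mesenchymal score were opposed at r = -0.84 (permutation p = 0.0015, adjusted p = 0.01), rho = -0.697, with r = -0.717 and no passing p without BT483 and HCC1806. The luminal and mesenchymal scores were opposed within the 7 lines of higher luminal score at r = -0.908 (exact permutation p = 0.0085, adjusted p = 0.029), rho = -0.821, and within the 7 of lower score at r = -0.859 (exact permutation p = 0.013, adjusted p = 0.04), rho = -0.857. Within the 7 lines of lower luminal score, that score and the basal epithelial score rose together at r = 0.886 (exact permutation p = 0.017, adjusted p = 0.047), rho = 0.786, and the luminal and estrogen-responsive scores were opposed at r = -0.773 (exact permutation p = 0.0067, adjusted p = 0.026), rho = -0.929. These 7 lines themselves lay in 2 groups on the luminal score. BT20, HCC1806 and HCC1428 ran from -0.92 to -1.26, and MDA-MB-231, BT549, Hs578t and MDA-MB-157 from -2.75 to -3.03. The clusters were not split again, so r in these lines does not tell a graded relation from a difference between the groups. Without the 2 farthest lines the 4 values for the luminal score, in the order given, were -0.795, -0.727, 0.976 and -0.531, and 0 of the 4 kept an adjusted permutation p under 0.05 with 5 lines left. So few lines have few orders, so such a p was hard to reach and its absence tells little. The lines left out were ZR75 and SKBR3 in the higher cluster and HCC1806 and BT20 in the lower. In the lower cluster HCC1428 then stood alone against the lines of lowest luminal score, so these values rest largely on HCC1428. Single lines also ended calls. The epithelial junction relation did not pass without HCC1806 (r = -0.736, adjusted permutation p = 0.13). The luminal and mesenchymal relation did not pass in the higher cluster without BT483, MCF7 or ZR75 (adjusted permutation p = 0.11, 0.051 and 0.056), or in the lower without BT483, BT20, HCC1806 or BT549 (adjusted permutation p = 0.052, 0.22, 0.075 and 0.058). The luminal and basal relation did not pass without BT483, Hs578t, MDA-MB-157, HCC1806, ZR75 or BT549 (adjusted permutation p = 0.058, 0.1, 0.17, 0.13, 0.052 and 0.16), and the luminal and estrogen-responsive one without BT20, HCC1806 or BT549 (adjusted permutation p = 0.3, 0.11 and 0.058). BT483 and ZR75 lie outside the lower cluster and changed its adjusted p only through the rest of the family. Proliferation and the mesenchymal score had r = 0.545 over 14 lines (permutation p = 0.042, adjusted p = 0.095), outside the threshold, and rho = 0.679 (permutation p = 0.009, adjusted p = 0.049), within it, with r = 0.737 without BT549 and Hs578t. Interferon-stimulated and HLA class I genes had r = 0.57 (permutation p = 0.033, adjusted p = 0.081) and rho = 0.53 (adjusted permutation p = 0.12), both outside the threshold, with r = 0.51 without BT474 and Hs578t. The 3-prime minus 5-prime difference of GAPDH had r = 0.393 with the mesenchymal score (permutation p = 0.15, adjusted p = 0.27), rho = 0.248, and r = 0.394 with proliferation (permutation p = 0.15, adjusted p = 0.27), rho = 0.437. Without MDA-MB-157 and BT549 these became -0.205, the opposite sign, and 0.188. The other 12 tests had r from -0.536 to 0.558 with an adjusted permutation p of 0.22 or more, and 8 of the 17 tests outside the threshold changed sign without their 2 farthest lines. By Pearson's r the number of relations past the threshold fell from 10 to 6 without BT483, 5 without HCC1806 and 6 without BT549, and to 2 with probe sets lacking an _x_at or _s_at suffix. By rho it fell from 5 to 1 without BT483 or HCC1806 and to 2 without MDA-MB-361, BT474, MCF7 or BT549. The number by rho was 3 without BT20, MDA-MB-157 or HCC1428 and 4 without Hs578t or T47D, and rose to 7 without MDA-MB-231.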

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

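The comparisons of lines within the classes commonly stated for them, the check by list medians and the tests of HCC1428 below were chosen only after results were seen. In each class of 4 to 7 lines and each of 16 lists, the highest or lowest line was compared with its neighbour by Dixon's gap test, 48 combinations of class and list in all, of which 8 had a line apart where chance would give 2.4, about 1 in 20. The combinations are not independent, because the 4 mesenchymal lines are all among the 7 receptor-negative ones and several lists vary together. The excess is therefore a description only.

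HCC1428 stood apart from the other 6 lines described as estrogen receptor positive in 3 scores. Its luminal identity score was -1.26 against 0.80 in the next line, its basal epithelial score 2.76 against 0.66, and its mesenchymal score 1.0 against -0.64. Among these 7 lines KRT19 was 6.53 in HCC1428 and between 13.35 and 14.15 in the other 6, and ESR1 was 7.83 in HCC1428 against 8.84 or more.

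A weak array or poor labelling is argued against as an account of HCC1428, since 0 of 9 control measures lay outside the range of the other 13 arrays; distribution measures, which RMA makes alike, were not used, and locally uneven hybridization cannot be seen from these values. For the low luminal genes, RNA of another line mixed at up to an equal share into a line that otherwise resembled the other 6 could lower a gene by at most 1, whereas the 14 luminal genes averaged -2.59 (SE 0.51) relative to those lines and 10 of them were lower by more than 1. That value restates the low score and bounds no larger share, and the test replaced an earlier count of 27 genes at least 3 below the other 6 lines, against 13 at most for another line. For the high basal epithelial and mesenchymal genes the same mixture cannot be told apart from a property of the line, because mixed RNA can raise low genes without such a bound and the 37 genes, at 2.38 (SE 0.36) above the other 6 lines on average, are what set the line apart. A mislabelled or changed culture cannot be told apart from a true property of the line, because there is no repeat array, and the highest correlation over all probe sets, 0.948 with HCC1806, has no repeat to be set against; the labels give no group for a biological account, so none was tested.

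ZR75 had the highest HLA class II presentation score of the 7 lines described as receptor positive, 3.54 against 1.40 in BT483. Among the 7 described as receptor negative, SKBR3 had the highest ERBB2 neighbourhood score, 2.59 against 0.06. Of the 4 lines described as mesenchymal, Hs578t had the highest estrogen-responsive score, 0.70 against -0.24, the highest serine and one-carbon score, 0.82 against -0.14, and the lowest proliferation score, -0.08 against 0.36. By the list median in place of the mean, 5 of the 8 stayed apart. The exceptions were the mesenchymal score of HCC1428 (0.35 against -0.17) and the estrogen-responsive and proliferation scores of Hs578t (0.49 against -0.23 and 0.01 against 0.30), the last with a mean and median of opposite sign.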

How the results depend on the processing

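Of the tests below, leaving out both HCC1428 and BT549 was chosen only after the results were seen. Among the values past a threshold that were followed under the settings run, 0 changed direction; of the 17 relations outside the threshold, followed only without their 2 farthest lines, 8 changed sign. Without the 2 lines, the 8 lines whose nearest line was still present kept it, so that count follows from the removal, and the estrogen receptor classes gave 242 genes in place of 49; other counts stayed within 1.5 times.

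Probe sets without an _x_at or _s_at suffix, a setting with fewer genes, gave 2854 genes differing at least 4-fold, 55 line-specific high genes, 2 relations and 30 genes between the receptor classes. A threshold of 8-fold gave 2326 genes, a gap of 2 log2 units 228 line-specific genes, arrays shifted to a common median 65 chromosomal regions, windows of 9 and 25 genes 21 and 117, and omitting the 2 farthest lines 4 relations. The genes between receptor classes numbered 28 with no filter, 0 without the 4 mesenchymal lines and 0 with the mesenchymal class as a covariate, where limma gave 709 and 763 genes at an unadjusted p under 0.05. About 1 in 20 of the 8623 genes tested would reach that unadjusted p by chance. Genes between mesenchymal classes numbered 85 without the 7 receptor-positive lines and 152 with the receptor class as a covariate. With an estimated correlation 0 lists remained between receptor classes and 2 between mesenchymal classes, which gave 8 lists without the 7 receptor-positive lines. Apart from fewer genes, lines or a stricter threshold, the cause was not tested.

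With each line left out in turn, relations past the threshold numbered 5 to 13, the lowest without HCC1806, with 6 without BT483 and 6 without BT549. Genes between receptor classes numbered 3 to 554: 3 without BT549, 4 without BT483, 5 without MDA-MB-361, 6 without Hs578t, 8 without MDA-MB-231, 9 without MDA-MB-157, 11 without MCF7, 12 without BT474, 25 without HCC1806, 26 without ZR75, 27 without T47D, 125 without BT20, 550 without SKBR3 and 554 without HCC1428. Genes between mesenchymal classes numbered 298 to 927, with 298 without Hs578t and 413 without BT549. The other ranges were 4212 to 4321 genes at 4-fold, 10 to 13 lines with the same nearest line (of 11 to 13 whose nearest line was still present), 87 to 112 line-specific high genes, 36 to 52 regions and 88 to 100 list scores outside the random range.

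Among values of single genes and lists over all settings, 714 line-specific gaps stayed within the spread of the controls and 44 moved beyond it. That spread is the median SD of the hybridization controls, 0.12, and not the 0.25 of the poly-A controls. Leaving out a line other than the next one cannot change a gap, and leaving out the next line can only widen it. The filter settings use the same values for gaps, so many of the 714 were fixed in advance. For region medians, 698 stayed within the spread of the controls and 156 moved. Of the list scores, 1822 stayed within their SE over genes and 131 moved, 99 of them luminal identity scores. Among relations 171 kept their side of the threshold and 36 became weaker, and 849 hypothesis genes kept theirs and 281 became weaker. By Pearson's r, ERBB2 with GRB7, GATA3 with FOXA1 and ESR1 with PGR passed in each of the 20, 21 and 22 alternatives run for them. Spearman's rho was followed only as a count of relations past the threshold. With 1 line left out, that count, 5 with all lines, ran from 1 without BT483 or HCC1806 to 7 without MDA-MB-231. The low-signal limit, 7.01, is the median of all values and not a measured background. RMA gives no detection calls, so these values do not tell low from absent expression.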

Other observations

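The tests of probe sets, of low genes with low neighbours, of HCC1428 and BT549 left out together and of the BT549 controls were chosen after the results were seen; the contrasts between classes, their splits and the test of neighbouring genes were fixed in advance, but the reading of that last test by its bootstrap interval was not. The classes are hypotheses from what is commonly stated about these lines and are not in the labels.

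As a hypothesis, the 7 lines described as estrogen receptor positive (BT483, MDA-MB-361, BT474, MCF7, T47D, ZR75 and HCC1428) were compared with the other 7 by limma, and 49 genes differed at an adjusted p under 0.05, 26 higher and 23 lower. AGR2 was higher by 6.61 ± 1.15 (SE, adjusted p = 0.025), ESR1 by 4.95 ± 0.78 (adjusted p = 0.02), GREB1 by 4.85 and CRABP2, a retinoic acid binding protein, by 4.05. SERPINA3, a serine protease inhibitor, was higher by 3.70 (adjusted p = 0.018). NT5E, an ectonucleotidase, fell by 4.87 ± 0.98 (adjusted p = 0.043), the ligand gene WNT5A fell by 4.83 and EGFR fell by 2.78. The other named genes were ABAT, FBP1, PYCARD, H2BC21, TM7SF2, CBFA2T3 and CEBPA, higher by 2.19 to 5.22, and COL4A2, which fell by 4.65, FXYD5, DAB2, PRKCA, GBP1, MT1E, RANGRF, PXDC1 and, with the smallest change, BIN1, which fell by 1.90. Only 1 of 100 splits of the 14 lines, the real one, gave as many genes, and the highest other gave 3. These were drawn from 1716 possible splits, so they show only that a random grouping seldom gives such a count. The splits do not test receptor status, because all 4 mesenchymal lines are among the 7 receptor-negative lines. The count depended on single lines: limma called 3 genes without BT549 and 554 without HCC1428, 550 without SKBR3 and 242 without HCC1428 and BT549, and 0 with the mesenchymal class as a covariate (763 of 8623 at an unadjusted p under 0.05, where chance would give about 1 in 20). Without any of BT483, MDA-MB-361, Hs578t, MDA-MB-231, MDA-MB-157, MCF7 or BT474 limma called 4 to 12, 25 to 27 without HCC1806, ZR75 or T47D, and 125 without BT20. Each of the 24 named genes lost its call in 2 to 15 settings, PXDC1 in the fewest and CBFA2T3, EGFR and MT1E in the most.

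In camera, 9 of 16 lists passed between the receptor classes. Luminal identity (1 gene past the threshold over all genes, 14 of 14 adjusted over the list alone) and estrogen-responsive genes (1, and 7 of 18 adjusted over the list alone) passed in the higher direction. So did epithelial junction (0, and 17 of 19 adjusted over the list alone), HLA class II (0 of 7 either way) and cholesterol synthesis (0, and 1 of 11 adjusted over the list alone). Mesenchymal genes (0, and 16 of 25 adjusted over the list alone) and hypoxia and glycolysis (0, and 3 of 15 adjusted over the list alone) passed in the lower direction. Proliferation (0 of 26 either way) and cancer-testis genes (0 of 8 either way) also passed in the lower direction as lists, with 0 single genes called. With an estimated correlation 0 lists held: adjusted p = 0.21 with an estimated correlation for luminal, estrogen-responsive, epithelial junction, mesenchymal, cholesterol and hypoxia lists, 0.25 for cancer-testis, 0.3 for proliferation and 0.45 for HLA class II. Calls also ended for HLA class II without ZR75 (adjusted p = 0.079), for cancer-testis without Hs578t (adjusted p = 0.055) or HCC1806 (adjusted p = 0.06), and, with probe sets lacking an _x_at or _s_at suffix, for cholesterol (adjusted p = 0.15) and hypoxia (adjusted p = 0.12). Without the 4 mesenchymal lines the mesenchymal and HLA class II lists did not pass (adjusted p = 0.12 and 0.1) and the basal epithelial list passed in the lower direction at the preset correlation (adjusted p = 0.0046), where limma called 0 genes over all genes (709 of 8623 at an unadjusted p under 0.05, where chance would give about 1 in 20) and no estimated correlation was run. The ERBB2 neighbourhood passed without SKBR3 (adjusted p = 0.006) or MCF7 (adjusted p = 0.044), and HLA class I without MDA-MB-231, T47D or ZR75 (adjusted p = 0.037, 0.039 and 0.023). With no filter HLA class I passed (adjusted p = 0.045) and HLA class II did not (adjusted p = 0.051). The other lists did not pass, with an adjusted p of 0.085 for HLA class I, 0.15 for the ERBB2 neighbourhood and 0.68 to 0.99 for basal epithelial, interferon-stimulated, serine and one-carbon, ErbB, and cell cycle inhibitor genes; for interferon-stimulated genes camera pointed up while the mean was -0.05, and for ErbB and cell cycle inhibitor genes it pointed up while the medians were -0.08 and -0.12.

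The 4 lines described as mesenchymal (Hs578t, MDA-MB-231, MDA-MB-157 and BT549) differed from the other 10 in 651 genes, 323 higher and 328 lower, by limma. SPARC was higher by 7.35 ± 0.44 (SE, adjusted p = 8.2e-08), the collagen crosslinking gene LOX by 6.79, VIM by 6.73 ± 0.40 (adjusted p = 8.2e-08) and the proteoglycan gene VCAN by 5.63. CDH1 fell by 8.23 ± 0.53 (adjusted p = 1.8e-07), EPCAM fell by 7.14, RAB25, a trafficking GTPase of epithelia, fell by 6.76 and ERBB3 fell by 5.92. Also named were AXL, PTX3, GNG11, PRR16, GJA1, TGFB1I1, EMP3 and NNMT, higher by 5.25 to 6.58, and KRT19, which fell by 7.64, AGR2, S100A8, SPINT2, ESRP1, RBM47, TMEM30B and, with the smallest change, TTC39A, which fell by 5.28. GJA1, at adjusted p = 0.046, lost its call in 15 of 24 settings, with no filter and without any 1 line other than MDA-MB-157, HCC1806 or T47D among them, and GNG11 in 5, without Hs578t and without BT549 among them. AXL, LOX, PTX3, PRR16, TGFB1I1, NNMT, AGR2 and TTC39A lost theirs only without the 7 receptor-positive lines or with the receptor class as a covariate, and the other 14 kept theirs in the settings run. Epithelial junction genes fell (18 of 19 past the threshold over all genes, 19 adjusted over the list alone) and mesenchymal genes rose (13 of 25, 23 adjusted over the list alone), and both calls held, at adjusted p = 0.00029 and 0.027 with an estimated correlation. Luminal genes fell (8 of 14, 11 adjusted over the list alone), at adjusted p = 0.071 with an estimated correlation. At the preset correlation camera called the proliferation list in the higher direction and the ERBB2 neighbourhood list in the lower. Of their genes, 0 of 26 and 0 of 12 passed the threshold either way. Both lists were at adjusted p = 0.78 with an estimated correlation. The ERBB2 neighbourhood list also did not pass without MDA-MB-231 (adjusted p = 0.052) or with probe sets lacking an _x_at or _s_at suffix (adjusted p = 0.069). The other 11 lists did not pass, at adjusted p from 0.085 for HLA class II to 0.98 for cell cycle inhibitors, whose mean of -0.07 and median of 0.04 differ in sign. Of 100 splits 1, the real one, gave as many genes, and the highest other, BT483, MDA-MB-361, BT474 and MCF7 against the rest, gave 64. The splits were drawn from 1001 possible ones and show only that a random grouping of 4 lines seldom gives such a count. They do not test what the 4 lines share. Without Hs578t 298 genes were called, 413 without BT549 and 85 without the 7 receptor-positive lines, where proliferation did not pass (adjusted p = 0.092). In that last setting 4 further lists passed at the preset correlation, estrogen-responsive genes in the higher direction (adjusted p = 0.023) and basal epithelial, HLA class II and ErbB genes in the lower (adjusted p = 0.00087, 0.033 and 0.0045). ErbB genes also did with no filter (adjusted p = 0.025). No estimated correlation was run in either setting. Of genes past the threshold in both contrasts, 10 were higher in receptor-positive and lower in mesenchymal lines, 7 the other way and 0 moved the same way, and because all 4 mesenchymal lines are among the 7 receptor-negative lines the contrasts are not independent.

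The 55 genes far lower in a single line could reflect one failing probe set, but in 21 of the 29 with another probe set above the limit every further probe set also lay at least 1 below the next line. The exceptions were RB1, GNAQ, MET, MED16, ALDH7A1, SEPTIN11, GLUL and ZMYM2. Loss of a chromosomal segment reaching the neighbouring genes predicted a median of -0.5 or lower for the 5 genes on each side. The median was -0.19 (bootstrap -0.26 to -0.10), with 47 of the 55 above -0.5, so a fall of that size was not typical of the set. It also lay below random gene sets (-0.07 to 0.08), inside which the advance rule had placed a set with no loss at all. Neither side of that rule was met and smaller falls were not bounded, so the test does not settle whether losses account for the low genes. For the 6 genes with neighbours below the 2.5th percentile of their line, AGAP1, TUBB6, ZMYM2, KLHL9, TENT4A and MEST, against 1.38 by chance, a loss cannot be told apart from joint regulation, because expression alone does not show copy number. The labels give no group for a biological account, so none was tested.

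BT549 had weaker 5-prime than 3-prime signal, and degraded sample RNA alone is argued against, since 3 of the 4 added poly-A controls (dap 3.18 against 2.12 on the next array, thr 3.06 against 2.24, phe 0.95 against 0.82, but not lys) also had their largest 3-prime minus 5-prime difference there. Shorter labelled product on that array is consistent with 5 of 6 control transcripts showing their largest difference on it, with GAPDH and ACTB among them. Genes whose probe sets lie far from the 3-prime end may therefore read low in BT549.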
